A study of Homo sapiens with 6 samples.

How the data were processed

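Total RNA of 6 samples was measured on Affymetrix Human Gene 2.0 ST arrays, per the series' design text, with 3 arrays of cells that express TDNC1 and 3 of cells that express a random control RNA. RNA was extracted with Trizol, treated with DNase and purified on silica columns, per the labels' protocols. The values were made with RMA in Affymetrix Power Tools, per the submitters' processing notes; the version, the annotation and the genome build are not given in the sources used here. The deposited values are on the log2 scale, judged from their range (lowest 0.79, highest 13.85). RMA subtracts a modelled background, gives all arrays the same probe distribution and summarises the probes of a transcript cluster by median polish, so a shift of most transcripts in 1 direction would be removed, and dim rows have compressed fold changes. Arrays have no sequencing depth; the number of arrays limits the precision.

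Rows were named through the platform annotation paired with the table. Of 53617 rows, 16098 were paired with 1 gene symbol, 0 with several, and 37519 are unnamed here, which does not mean that they have no gene. The entrez identifiers of all 16098 were found in the GRCh38.p14 gene table, which gave current symbols, gene types and gene order. The named rows cover 14884 symbols, 11916 of them protein-coding, 1398 long noncoding RNAs and 1072 microRNA genes. All rows were tested, including 3575 numbered below the first named row, which may hold control probes. No coordinates are printed because the build of the array annotation is not given.

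Groups were taken from the sample titles. TDNC1 was compared with the control by limma 3.58.1 in R 4.3.3 (lmFit and eBayes, trend and robust off, two-sided) over all 6 arrays with no covariate, and a row was called at a Benjamini-Hochberg adjusted p under 0.05. A rise is a higher value in TDNC1. The choices of test, gene lists, named genes and alternatives were fixed before the data were examined, except where stated. Of 41 gene lists, 36 had at least 5 measured members and were tested with limma's camera (preset correlation 0.01, 1 row per symbol, the one with the highest mean), and chromosomes were tested as sets in the same way. With a preset correlation, camera takes the genes of a list as nearly independent, so camera with an estimated correlation and fry, a rotation test, were run beside it. Both calls were lost in each. The estimated setting decides little with so few arrays, as 0 of the 36 lists had an unadjusted p under 0.05 in it. Heat shock genes had an estimated correlation of -0.0539, below the preset, and their camera adjusted p still rose from 0.0973 to 0.761. A call lost there therefore does not by itself show that correlation between genes made it. The 2 called lists had estimated correlations well above the preset, however. These were 0.224 for box H/ACA small nucleolar and Cajal body RNAs and 0.417 for cholesterol biosynthesis. Correlation between genes thus stays open as a source of both calls. Lists of replication-dependent histones, mitochondrially encoded transcripts, box C/D RNAs, spliceosomal RNAs and olfactory receptors had too few measured members (at most 1) and were not analysed here.

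Genes were named by this rule. Among rows with 1 symbol, past the threshold and with no overlap between the groups, the 15 largest rises and falls were named. Where fewer passed in a direction, those with the smallest p followed, up to 10 in all, as values that did not pass. Up to 4 members with the smallest p were taken from each list described, with ACTB, GAPDH, TBP and HPRT1 as control genes. Genes named outside it were chosen after their values were seen. These were the neighbours of LOC646736, and in the closing section EGR1, CCN2 and FOS. Genes and list members named only without TDNC1 replicate 3 are also outside it. They were picked by the same steps from the fit without that array. With that array included, the groups overlapped for several of them, such as DDIT4, SH3BGRL3, CDK2AP2 and CBX6. For others, such as ARRDC4 and PDE8B, they did not.

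The limma step was tested on simulated arrays of the same 53617 rows, 3 against 3, in 5 draws with 250 changed rows of each size. It recovered 4.0% of log2 changes of 0.5, 80.0% of changes of 1, 99.2% of changes of 2 and 100% of changes of 4, with 34 false calls in all. The simulated noise was independent and no array stood apart. Each draw also held many large changes, which loosens the adjusted threshold. These shares are therefore not those of the deposited arrays, where 158 rows had a log2 change over 1 in size and 1 row was called. There, row 16771478 had a change of -2.26 (SE 0.28) and a limma adjusted p of 0.631. The camera step called a list of 25 genes raised by 0.3 in 5 of 5 draws, and 1 of 150 unchanged lists. The simulated rows were independent and the lists random, so lists of correlated genes were not tested. The estimated correlation of the immediate early list was 0.696, and another split of the deposited arrays gave 7 called lists. The low number of false list calls therefore does not carry over.

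The alternatives were a second quantile normalization, median centring, a filter on dim rows, 1 row per gene, eBayes with trend and robust, array weights, a replicate block, each array left out in turn, a looser threshold of 0.1, a minimum change of 1.5-fold, and for lists an estimated correlation, fry and all rows of a symbol. Chosen after seeing the data were cyclic loess, cyclic loess together with leaving out TDNC1 replicate 3, leaving out that array with an estimated correlation, leaving out both arrays numbered 3, and leaving out the rows below the first named one.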

Results

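Gene expression was measured in HEK293 cells, a human embryonic kidney line, of the Flp-In T-REx type, in which a construct is inserted at a fixed site of the genome. The cells stably carried either TDNC1 or a random control RNA, and the stable clones of each kind were pooled before RNA extraction. The labels do not say what TDNC1 stands for, and whether the inducer was added is not given in the sources used here. Total RNA was hybridised to Affymetrix Human Gene 2.0 ST arrays, 3 for TDNC1 and 3 for the control. The table held 53617 rows, each the log2 expression value of 1 transcript cluster. The medians of the 6 arrays lay between 5.16 and 5.22. The labels call the arrays of a group biological replicates without saying whether they came from separate cultures or pools, so the p-values measure the spread between these samples, which can be partly technical. The precision is limited by the 3 arrays per group. The comparison asks which transcripts differ in cells that express TDNC1, as the series title states.

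The long noncoding RNA LOC646736 was higher in the TDNC1 cells than in the control cells by 6.06 on the log2 scale (SE 0.13, 95% interval 5.76 to 6.36), or 66.7-fold. Its expression was 9.73 ± 0.10 (SD, n = 3) in TDNC1 and 3.67 ± 0.20 (SD, n = 3) in the control. All 3 TDNC1 arrays lay far above all 3 control arrays, at 9.71, 9.85 and 9.65 against 3.56, 3.56 and 3.90. In the TDNC1 arrays it lay above 96.2%, 96.6% and 96.1% of all rows, and in the control arrays above 21.0%, 21.2% and 26.6%. The control values are thus among the dim rows, where array values flatten, so the fold can be understated. LOC646736 was the 1 row of 53617 that passed limma's moderated test after Benjamini-Hochberg adjustment (adjusted p = 1.829e-05). The next smallest adjusted p was 0.631. No row bears the name TDNC1 here.

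LOC646736 lies on chromosome 2 in the GRCh38.p14 gene table, which was used for names and gene order. Its nearest measured neighbours did not pass the test. The insulin receptor substrate IRS1 had a log2 change of -0.05 (SE 0.13), the rhomboid protease gene RHBDD1 -0.11 (SE 0.10), and NYAP2, on the other side, 0.38 (SE 0.11). The median over the 10 nearest measured genes was 0.01.

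No other gene was called with all 6 arrays, and the genes with the smallest p in each direction are given as values that did not pass (limma, adjusted p = 0.631 for each). Those with higher values in all 3 TDNC1 arrays included several microRNA precursors. The row of MIR200C, a member of the miR-200 family tied to the epithelial state, stood at 4.38 ± 0.17 in TDNC1 and 3.37 ± 0.25 in the control, a log2 change of 1.01 (SE 0.15). Its control mean lies below the lower quartile of every array (lowest 3.77), among the dim rows. MIR4688 had a change of 0.60, MIR548I1 of 0.59 and MIR548I2 of 0.54. Among protein-coding genes, OSTN, which encodes the secreted peptide osteocrin, had a change of 0.85 (SE 0.15). The septin gene SEPTIN3 had 0.74 (SE 0.15), the surface glycoprotein gene CD24 0.65 (SE 0.13) and MAP6, which encodes a microtubule-stabilising protein, 0.53 (SE 0.10). The pseudogene NUDT9P1 had 0.72.

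Among the genes with lower values in all 3 TDNC1 arrays, BMP2, a growth factor of the bone morphogenetic protein family, stood at 5.41 ± 0.18 against 6.22 ± 0.11, a log2 change of -0.82 (SE 0.12). The long noncoding RNAs LINC01061 and LOC729737 had changes of -0.66 and -0.49. NUP214, a nuclear pore component, had -0.50 (SE 0.10), the keratin-associated protein gene KRTAP21-2 -0.61, the co-repressor gene RIPPLY1 -0.45 and VSTM5 -0.44. CXCL10, an interferon-induced chemokine, had -0.40 (SE 0.09). MIR624 had -0.55. The 2 rows of MIR499A disagreed, with changes of -0.71 and 0.49. The rows given for NUP214, LINC01061 and LOC729737 are not the brightest rows of these genes. The changes of their brighter rows are not given here, so these values stand for the rows alone.

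Of all rows, 4129 (7.70%) had an unadjusted p under 0.05 in limma, 2006 higher and 2123 lower in TDNC1. Without TDNC1 replicate 3 it was 7770 rows (14.49%). The groups did not overlap in 7069 rows (13.18%), where chance gives 10%. As control genes, GAPDH had a log2 change of 0.01 (SE 0.09), which was slightly below 0 when TDNC1 replicate 1 or TDNC1 replicate 2 was left out. HPRT1 had 0.14 (SE 0.09) and the TATA-binding protein gene TBP -0.28 (SE 0.11), with adjusted p of 0.981, 0.699 and 0.642. ACTB is not named in the table used here.

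**Figure D1:**
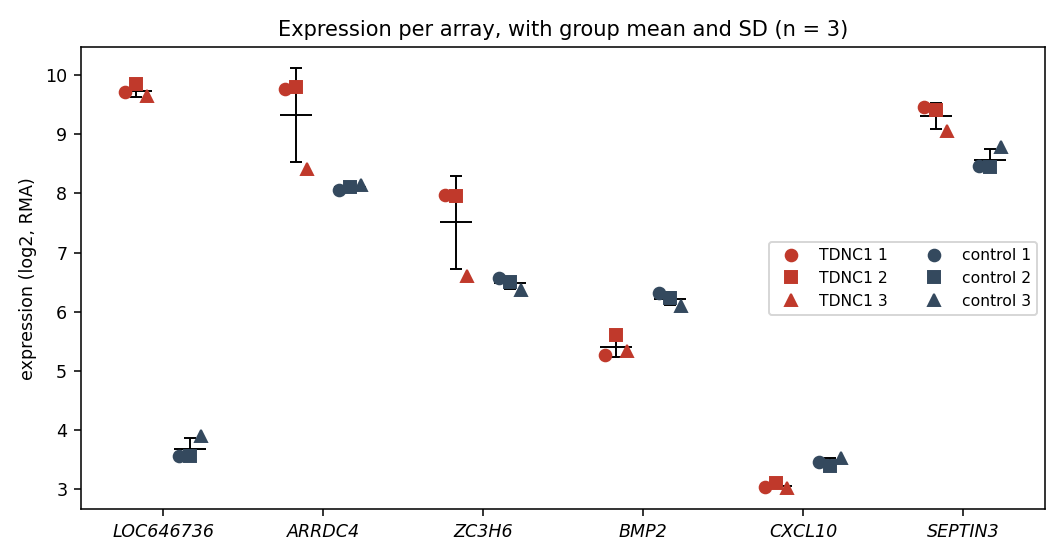
Log2 expression (vertical axis) of 6 genes in each of the 6 arrays, with red symbols for TDNC1, dark blue for the control and 1 symbol shape per replicate number; lines and bars give the group mean and SD (n = 3). LOC646736 is near 9.7 in all 3 TDNC1 arrays, while ARRDC4 and ZC3H6, chosen from the result without TDNC1 replicate 3, are high in TDNC1 replicates 1 and 2 only.

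Small Cajal body RNAs, which guide the modification of spliceosomal RNAs, were higher as a group in TDNC1. The list was fixed as box H/ACA small nucleolar and Cajal body RNAs, but all 23 measured members are Cajal body RNAs (SCARNA). The median log2 change over the 23 measured RNAs was 0.28 and the mean 0.25, and 17 had positive values. None passed the test by itself, over all rows or adjusted over the list alone, and 5 had an unadjusted p under 0.05, all higher. SCARNA7 had a change of 0.61 (SE 0.14), SCARNA4 0.79 (SE 0.25), SCARNA22 0.49 (SE 0.13) and SCARNA6 0.47 (SE 0.15). The list passed limma's camera test with the preset correlation (adjusted p = 0.00644), but not with an estimated correlation (adjusted p = 0.912) or in fry (adjusted p = 0.541). Its array means relative to the control mean were 0.21, 0.38 and 0.15 in TDNC1 and -0.14, 0.02 and 0.12 in the control. The call ended without TDNC1 replicate 2 (adjusted p = 0.0720) and without control replicate 1 (adjusted p = 0.107), and the adjusted p ran from 0.000123 to 0.912 over all alternatives.

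Genes of cholesterol biosynthesis also had a higher mean in TDNC1, with a median log2 change of 0.16 and a mean of 0.17 over 17 measured genes, 14 of them positive. The groups overlapped, as control replicate 3 (0.15) lay above TDNC1 replicates 1 and 2 (0.14 and 0.10) in the list's array means. None passed by itself, over all rows or adjusted over the list alone, and 5 had an unadjusted p under 0.05, all higher. HMGCS1, which makes the HMG-CoA that enters the pathway, had a change of 0.61 (SE 0.14). INSIG1, which retains the sterol sensor in the endoplasmic reticulum, had 0.44 (SE 0.15), the sterol oxidase gene MSMO1 0.35 (SE 0.10) and the sterol carrier gene STARD4 0.35 (SE 0.10). The list passed camera with the preset correlation (adjusted p = 0.0109), but not with an estimated correlation (adjusted p = 0.912) or in fry (adjusted p = 0.541). Its array means relative to the control mean were 0.14, 0.10 and 0.26 in TDNC1 and -0.11, -0.04 and 0.15 in the control, highest in replicate 3 of both groups. The call ended without TDNC1 replicate 3 (adjusted p = 0.452), without control replicate 1 (0.148), without control replicate 2 (0.0518) with array weights (0.0532) and without both arrays numbered 3 (0.0511), over a range of adjusted p from 0.000114 to 0.912.

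The remaining lists did not pass camera with all 6 arrays, and their members are given as values. Heat shock genes had a mean log2 change of -0.18 over 10 genes and metallothioneins, the metal-binding stress proteins, -0.23 over 9 genes, 1 of them a pseudogene (adjusted p = 0.0973 for each). The inducible HSP70 genes HSPA1A and HSPA1B had -0.59 and -0.61. They are near-identical copies that the probes may not tell apart. Both count among the 10 genes, so the list can hold the same signal more than once. The median over the 10 genes was -0.21. With all rows of a symbol used, where HSPA1A and HSPA1B enter with 5 rows each, the heat shock mean was -0.38 and the list passed camera (adjusted p = 1.225e-06, in a range up to 0.761 over all alternatives, reached with an estimated correlation). Rows 17026318, 17027994 and 17030820 of HSPA1A hold the same values in all 6 arrays. Camera counts such rows as separate members, so this p counts the same signal more than once and does not measure support for the list. MT2A had -0.55 and MT1X -0.65. In TDNC1 replicate 3, MT1X stood at 8.71, within the range of the controls (8.52 to 8.78). HOX genes had a mean of -0.10 over 27 genes, and genes of hypoxia and glycolysis 0.11 over 17 genes (adjusted p = 0.115 for each). Growth and stress lists with adjusted p above 0.2 included mitosis and G2/M (mean 0.05), DNA replication (-0.02), DNA repair (0.04), the ATF4 and unfolded protein response (0.09), NF-kB genes (-0.04) and immediate early genes (-0.13). Among them, ASNS, which makes asparagine, had a log2 change of 0.56 (SE 0.18) and DDIT3, the stress factor CHOP, 0.49 (SE 0.16). Both values rest mostly on TDNC1 replicates 1 and 2. ASNS stood at 9.44 and 9.46 in them and at 8.84 in TDNC1 replicate 3, where the highest control was 8.75. DDIT3 stood at 5.04 and 5.10 in them and at 4.577 in TDNC1 replicate 3, below control replicate 2 at 4.584. Of the lists of noncoding RNA, the microRNA list of 1098 genes, 26 of them long noncoding host genes of microRNAs, had a mean of -0.03 (adjusted p = 0.178) and 458 long intergenic noncoding RNAs -0.02 (adjusted p = 0.401).

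The interferon response list of 24 measured genes went both ways. IFIH1, a sensor of double-stranded RNA, had a log2 change of 0.39 (SE 0.09), and the membrane proteins IFITM1 and BST2, which restrict viruses, had 0.63 (SE 0.18) and 1.03 (SE 0.33), while CXCL10 had -0.40. The value of BST2 rests on TDNC1 replicates 1 and 2, at 5.71 and 5.90. In TDNC1 replicate 3 it stood at 4.81, below control replicate 3 at 4.96. No member passed over all rows, and 2 did when adjusted over the list alone, CXCL10 and IFIH1, in opposite directions. CXCL10 is a dim row, with means of 3.06 in TDNC1 and 3.46 in the control, below the lower quartile of every array (lowest 3.77). Without TDNC1 replicate 3, 0 members passed adjusted over the list alone. With all 6 arrays no other list had a member that passed adjusted over the list alone. Camera gave an adjusted p of 0.997, and fry's test for change in either direction gave 0.000497, the 1 list past the threshold in that test. For 4 lists the median, mean and test differed in sign. The interferon list had a median of -0.004, a mean of 0.06 and a test toward lower values, p53 targets 0.01, -0.004 and higher, extracellular matrix genes 0.02, -0.03 and lower, and kidney markers -0.002, 0.04 and higher.

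Markers of other cell types did not pass. Fibroblast markers had a mean log2 change of 0.07 (adjusted p = 0.711), blood cell markers -0.04 (0.694) and epithelial markers 0.03 (0.743) in camera. No chromosome of 23 tested as a set passed camera (smallest adjusted p = 0.880); 0 had an unadjusted p under 0.05, with the preset or an estimated correlation.

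TDNC1 replicate 3 stood apart from the other TDNC1 arrays over the genome and lay nearest to control replicate 3. The median absolute difference between TDNC1 replicates 1 and 2 was 0.134 on the log2 scale. TDNC1 replicate 3 differed by 0.188 and 0.177 from them, by 0.136 from control replicate 3 and by 0.161 and 0.156 from control replicates 1 and 2. Control replicate 3 also stood apart from control replicates 1 and 2, by 0.162 and 0.160, where these differed by 0.1355 from each other. In a principal component analysis, the first component (32.87% of the variance) placed TDNC1 replicates 1 and 2 at -44.96 and -36.15. TDNC1 replicate 3 lay at 20.33 and the controls at 16.77, 26.66 and 17.35. The second component (20.56%) placed TDNC1 replicate 3 at 27.89 and control replicate 3 at 29.45, apart from control replicates 1 and 2 at -21.8 and -31.95. TDNC1 replicates 1 and 2 lay at -1.07 and -2.53 on it.

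**Figure D2:**
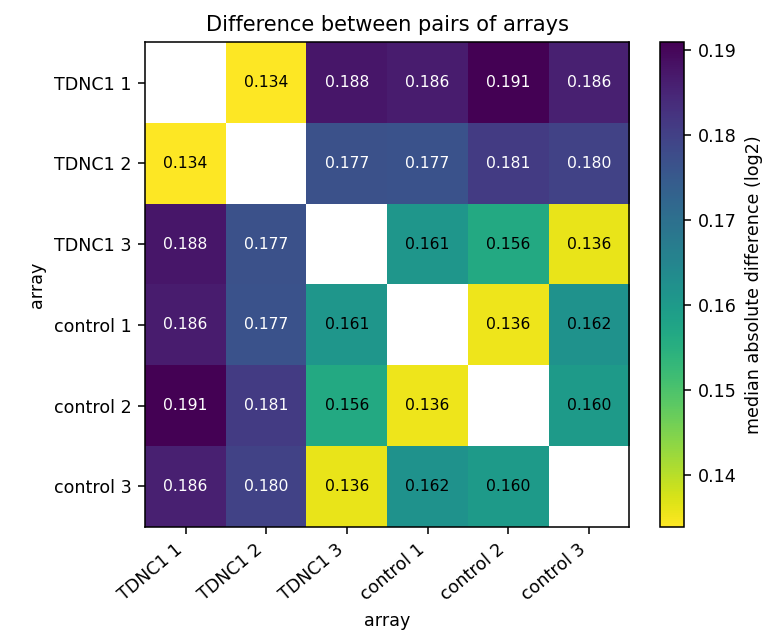
Median absolute difference in log2 expression over all rows for each pair of the 6 arrays (both axes list the arrays), with darker cells for larger differences. TDNC1 replicate 3 is nearest to control replicate 3 (0.136), and TDNC1 replicates 1 and 2 are nearest to each other (0.134).

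Without TDNC1 replicate 3, an alternative fixed before the data were examined that sets 2 arrays against 3, 23 rows passed limma's test, 19 higher and 4 lower in TDNC1, against 1 with all arrays. LOC646736 was again among them. Of the others, 20 have no gene name here, with log2 changes up to 3.60 (row 16730701) and down to -2.58 (row 16771478). The named ones were ARRDC4, an arrestin-family gene that limits glucose uptake, and ZC3H6, which encodes a zinc finger protein. ARRDC4 was higher by 1.68 (SE 0.09, adjusted p = 0.0163) and ZC3H6 by 1.49 (SE 0.10, adjusted p = 0.0303). ARRDC4 stood at 9.76 and 9.80 in TDNC1 replicates 1 and 2, at 8.41 in TDNC1 replicate 3 and at 8.06, 8.11 and 8.14 in the controls. ZC3H6 stood at 7.97 and 7.96, at 6.60, and at 6.56, 6.49 and 6.37. Over all alternatives the highest adjusted p was 0.919 for both, and the lowest 0.0157 and 0.0283. With control replicate 3 left out as well, which leaves 2 arrays per group, LOC646736 alone passed, and 8035 rows had an unadjusted p under 0.05.

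Genes that came next without TDNC1 replicate 3 did not pass (limma, adjusted p from 0.0563 to 0.0847). Those with higher values were DDIT4, a stress-induced inhibitor of the mTOR pathway, with a log2 change of 1.16 (SE 0.10), the cyclic nucleotide phosphodiesterase gene PDE8B with 0.99, IMPACT, a regulator of GCN2, with 1.03, NRN1 with 0.93, the serine protease gene HTRA1 with 0.98, TMEM150C with 1.02 and LOC100240735 with 1.23. Those with lower values were SH3BGRL3 with -1.38, FAM174C with -1.29, CDK2AP2 with -1.24, the Polycomb gene CBX6 with -1.12, the phosphatidylinositol synthase gene CDIPT with -1.07, SLC38A12 with -1.03, CIRBP-AS1 with -0.93, the lysosomal gene CTSA with -0.80, and HSPA1B and HSPA1A with -0.95 and -0.91. These 2 values come from other rows than those given with all arrays, which had -0.84 and -0.83 here. In TDNC1 replicate 3, DDIT4 stood at 7.52, where the control mean was 7.67, and SH3BGRL3 at 7.77, where it was 7.64. The row of LOC100240735 is not the brightest of its gene, and the brighter row is not given here.

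Without the same array, 6 lists passed camera with the preset correlation, and 0 with an estimated correlation (adjusted p = 0.833 for each, 0 lists with an unadjusted p under 0.05). Lower in TDNC1 were immediate early genes (mean log2 change -0.34, adjusted p = 0.00179), HOX genes (-0.18, 0.00363), metallothioneins (-0.32, 0.0382) and heat shock genes (-0.23, 0.0490). Higher were Cajal body RNAs (0.29, 0.0144) and genes of hypoxia and glycolysis (0.15, 0.0490), and the Cajal body RNA list was the 1 also called with all arrays. Adjusted over the list alone, 5 HOX genes, 2 metallothioneins, 5 heat shock genes, 4 hypoxia genes, 6 Cajal body RNAs and 0 immediate early genes passed; over all rows 0 members of these lists did. Members also passed that way in lists that camera did not call, the highest number in the ATF4 and unfolded protein response list, with 8 of 18 (camera adjusted p = 0.704). In that list 6 genes were higher and 4 lower at an unadjusted p under 0.05. HOXB5, a homeobox patterning gene, had a change of -0.81 (SE 0.15) and its neighbour in function HOXB2 -0.71 (SE 0.11), while HOXB4 had 0.31 (SE 0.11). MT1X had -0.99 (SE 0.11) and MT2A -0.79 (SE 0.09), while MT1H had 0.36 (SE 0.12). HSPA1A and HSPA1B, the near-identical copies, had -0.83 and -0.84, and the median of the heat shock list was -0.17. Both copies count as members, so the heat shock call and its 5 genes can hold the same signal more than once. At an unadjusted p under 0.05, 8 HOX genes were lower and 1 higher, 4 metallothioneins lower and 1 higher, 4 heat shock genes lower and 1 higher, 7 immediate early genes lower and 0 higher, 6 hypoxia genes higher and 0 lower, and 9 Cajal body RNAs higher and 1 lower. VEGFA, the angiogenic growth factor, had 0.49 (SE 0.11) and the glycolytic gene PGK1 0.39 (SE 0.09). DUSP6, a phosphatase that is induced by and acts on ERK, had -0.85 (SE 0.17). The immediate early list had array means of -0.36 and -0.33 in TDNC1 replicates 1 and 2, 0.31 in TDNC1 replicate 3, and -0.18, -0.16 and 0.35 in control replicates 1, 2 and 3, highest in replicate 3 of both groups. Leaving out TDNC1 replicate 3 alone therefore sets the groups out of balance for this list. Without both arrays numbered 3, a setting chosen after seeing the data, its mean log2 change was -0.17 (camera adjusted p = 0.0224). In that setting Cajal body RNAs (0.35, 0.00289), HOX genes (-0.15, 0.0200), genes of hypoxia and glycolysis (0.19, 0.0224) and metallothioneins (-0.33, 0.0292) also passed, and heat shock genes (-0.22, 0.0964) did not. Over all alternatives, the highest adjusted p of these lists was 0.761 to 0.940.

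**Figure D3:**
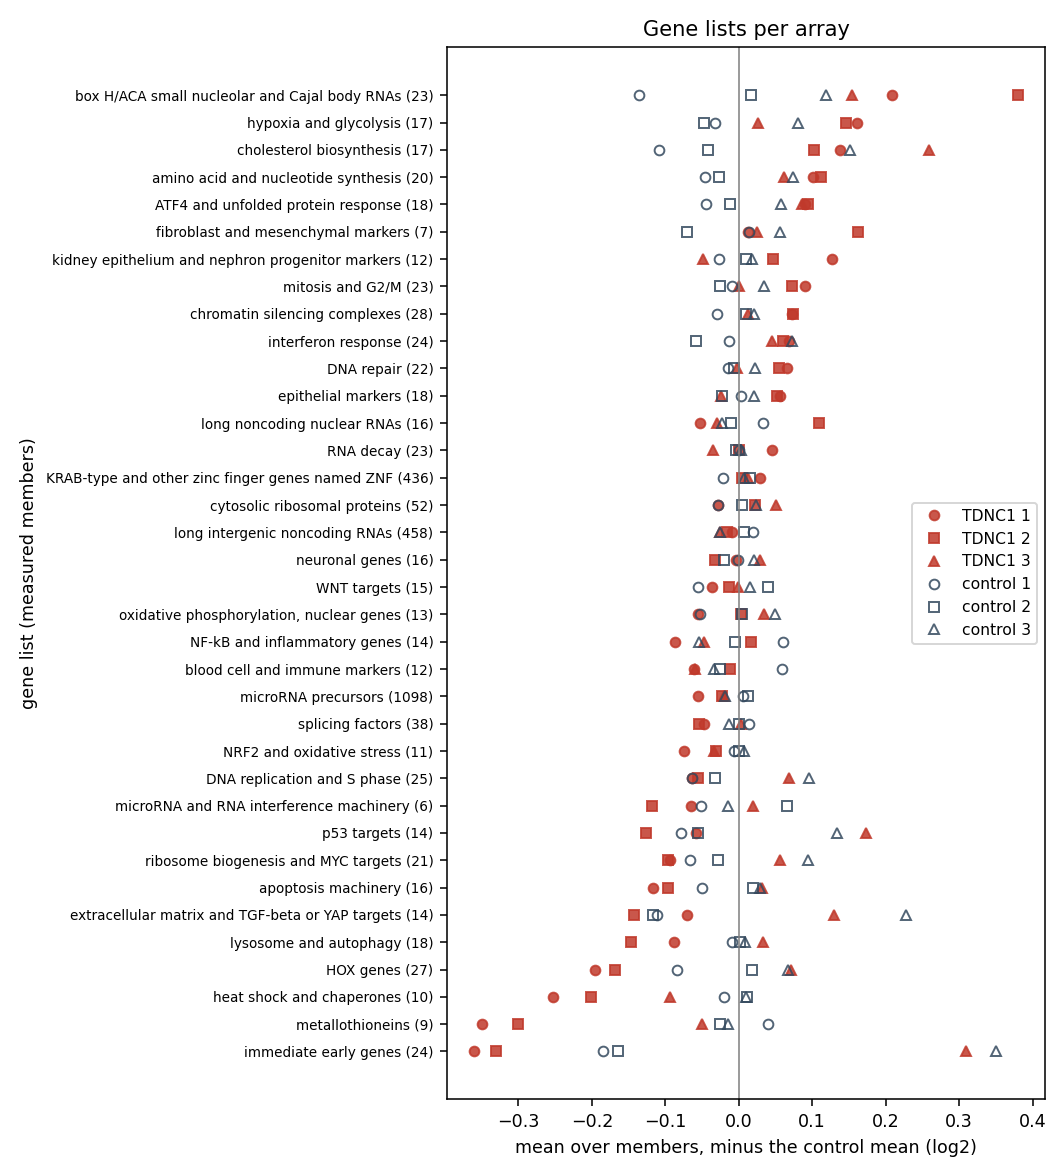
Mean log2 value over the measured members of each gene list (vertical axis, number of members in brackets) in each array, relative to the mean of the 3 controls (horizontal axis, log2), with filled red symbols for TDNC1, open blue ones for the control and 1 shape per replicate number. Immediate early genes are highest in replicate 3 of both groups (0.31 and 0.35), and metallothioneins are lowest in TDNC1 replicates 1 and 2 (-0.35 and -0.30).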

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

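LOC646736 passed under all 17 alternatives run on it, with log2 changes from 6.002 to 6.217 and adjusted p from 2.625e-07 to 0.00635. The 1 called row became 1 to 23 rows when each array was left out: 23 without TDNC1 replicate 3 and 2 without control replicate 3, where the added row, 16763966, is unnamed (log2 change 2.46, adjusted p = 0.00670). Cyclic loess with TDNC1 replicate 3 left out gave 24. The 2 called lists became 1 with array weights, which kept the Cajal body RNA list, 0 with an estimated correlation (0 at an unadjusted p under 0.05) and 0 in fry (3 at an unadjusted p under 0.05). Leaving out each array gave 1 to 6 lists; without control replicate 1 the call was HOX genes (lower, adjusted p = 0.0386) and neither main list. With TDNC1 replicate 3 left out, cyclic loess gave 5 lists and an estimated correlation 0 (0 at an unadjusted p under 0.05). With the arrays numbered 3 of both groups left out, 1 row and 5 lists passed, 1 of the lists shared with the main result. The cause was not tested. Lists at 3 gained the microRNA list (dim filter, lower), heat shock genes (all rows, lower) or hypoxia genes (without control replicate 3, higher). No chromosome passed in any alternative.

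With the replicate block, 1 row, 3 lists (immediate early genes added, lower, adjusted p = 0.0309) and 0 chromosomes passed. The numbers share no origin in the labels, and deviations of same-numbered arrays correlated at 0.0359, -0.00129 and 0.0468. TDNC1 replicate 2 was closest to control replicate 1 by this measure. By the correlation of whole arrays, TDNC1 replicate 3 and control replicate 3 were each other's closest array (0.990), so a link between the arrays numbered 3 is not excluded.

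For single named genes, 696 of 700 values kept their side of the threshold and 4 became calls (ARRDC4 and ZC3H6 without TDNC1 replicate 3, before and after cyclic loess). For single lists, 688 of 718 did, 18 became calls and 12 lost them. Uncalled values that changed sign, 2 for genes (GAPDH) and 46 for lists, are counted as kept. No called value changed sign. Cyclic loess, the settings that join 2 choices and the one without both arrays numbered 3 were chosen after seeing the data. Dim rows, such as LOC646736 in the controls, limit how well a fold is known.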

Other observations

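The tests of a wrong label, a mixed sample, a shared day, a regional change, the construct, the immediate early genes and the brightness trend, and the cyclic loess setting, were chosen after the result was seen; the counts over other splits of the arrays were set before.

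Immediate early genes, which respond within minutes to serum and growth factors, were higher in replicate 3 than in replicates 1 and 2 within each group. The mean log2 difference over 24 genes was 0.525 in the control, with 23 genes higher, and 0.654 in TDNC1, with 22 genes higher. EGR1, a zinc finger factor of this class, stood at 7.51 and 7.50 in control replicates 1 and 2 and at 9.08 in control replicate 3. In TDNC1 it stood at 6.79, 6.84 and 9.13. CCN2, a target of serum and YAP signalling, stood at 5.78, 5.67 and 7.03 in the control and at 5.84, 5.70 and 7.31 in TDNC1. The dimmer row of CCN2 had no such gap in the control, at 1.90, 2.61 and 2.55. FOS did not follow in the control, where its 2 rows stood at 6.10, 5.97 and 6.09 and at 5.99, 5.92 and 5.603. In TDNC1 they stood at 5.98, 5.93 and 6.27 and at 5.67, 5.63 and 5.73. A day or handling step shared by the arrays numbered 3 stays open: the values 0.525 and 0.654 are the observation itself and do not test it, and the labels give no day. No biological explanation was tested.

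Genes of lysosome and autophagy went both ways, with 9 of 18 measured genes higher and 9 lower in TDNC1 and a median log2 change of -0.004. CTSA had a log2 change of -0.56 (SE 0.20), CTSD -0.62 (SE 0.27) and LAMP1 -0.38 (SE 0.16), while TFEB, which switches lysosomal genes on, had 0.27 (SE 0.11). These values depend on TDNC1 replicate 3, without which CTSA had -0.80, CTSD -0.95, LAMP1 -0.56 and TFEB 0.34; in that array CTSD stood at 10.08, where the control mean was 10.03. The list's array means relative to the control mean were -0.09, -0.15 and 0.03 in TDNC1 (camera adjusted p = 0.743, and 0.301 without TDNC1 replicate 3). The serine enzyme gene PSPH (0.36, SE 0.10) and the arginine pathway gene ASS1 (0.71, SE 0.20) had higher values in the list of amino acid and nucleotide synthesis, of which 14 of 20 genes were positive (adjusted p = 0.382).

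TDNC1 replicates 1 and 2 shared changes that TDNC1 replicate 3 lacked. Over 14883 genes without LOC646736, the changes of replicates 1 and 2 against the control mean had a covariance of 0.0449, where the shared controls alone give 0.0081; for replicates 1 and 3 it was 0.0074 and for 2 and 3 0.0086. A control sample under a wrong label is argued against by LOC646736, which stood 5.974 above the control mean in TDNC1 replicate 3, and control cells mixed in by its level at 0.914 of that in replicates 1 and 2, where the other 22 rows called without this array kept a median share of 0.0739 (quartiles -0.05 and 0.19). A day that adds alike to both groups is argued against, as the only cause, by a slope of 0.141 over genes. The upper limit was 0.153, where 0.609 would be reached with such a day alone. That limit takes genes as independent, and each group has 1 array numbered 3. A partial share of such a day stays open, as the second principal component placed the arrays numbered 3 together, at 27.89 and 29.45. Brightness-dependent bias is argued against by a trend of at most 0.0225 between these arrays at the 22 rows, where the smallest difference was 0.674. The 24 rows called after cyclic loess decide little, as it moved no value by more than 0.106. A difference in culture state or clone pool between TDNC1 replicates 1 and 2 and the other arrays stays open, as does an effect of TDNC1 that replicate 3 lacked; neither was tested.

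LOC646736 was the called row with all 6 arrays. A change of the whole region is argued against by its 10 nearest measured genes, with a median log2 change of 0.0114 and a largest of 0.385. The largest is that of NYAP2, the nearest measured gene on its side, where the groups did not overlap. Several of the 10 are dim and could hide a small change. The brighter ones, IRS1, RHBDD1, MFF, CUL3 and AGFG1, had changes from -0.11 to 0.13. That the TDNC1 construct carries LOC646736 sequence stays open, as does an effect of TDNC1 on the gene itself. The gap of 5.747 between the lowest TDNC1 and the highest control array is the observation itself and tests neither, and the labels do not give the sequence of TDNC1.

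The 6 arrays can be split into 3 and 3 in 10 ways, too few for a share under 0.05. For called rows, the real split gave 1 and the highest other 1, and 2 splits gave as many. For lists, the real split gave 2 and the highest other 7, and 6 splits gave as many. For chromosomes, the real split gave 0 and the highest other 1, so all 10 gave as many.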
